A study of Mus musculus with 15 samples.

How the data were processed

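Kidney RNA was measured on a 1-colour expression array in 15 mice aged about 6 months, of which 8 lacked Grhl1 and 7 were wild type. Grhl1 encodes a grainyhead-like transcription factor of epithelia. Per the labels' protocols, total RNA was isolated with an organic extraction reagent, and 500 ng of it was labelled with the Ambion WT Expression kit, which primes along the whole transcript, and biotin. The deposited values are log2 summaries per probe set made by the authors with robust multi-array average (RMA), which subtracts background, equalises the distributions of the arrays and fits the probes of a set together, per the submitters' processing notes. The software and its version were not given in the sources used here. Because RMA forces the arrays to the same distribution, a change of most transcripts in 1 direction would be removed before deposit, and probe sets with dim probes are compressed toward the background, so that their differences understate the change in the transcript. No scanner files were analysed here, so that a probe set's signal over background could not be tested, and the number of arrays limits the precision of each value.

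The table held 41345 probe sets with values from 1.28 to 13.90, and the medians of the arrays lay between 5.51 and 5.59. The pairwise correlation of arrays ranged from 0.978 to 0.996, and no 2 arrays held identical values. The platform annotation paired 25335 probe sets with genes, 23521 of them with exactly 1 gene symbol and 1814 with several, and 16010 probe sets were unnamed here. The 23521 probe sets with 1 symbol were tested, without a filter on dim probe sets, and they covered 22180 genes. Symbols were updated by Entrez ID to the RefSeq genes of the assembly GRCm38.p6 for 23328 of these probe sets, and 193 kept the annotation's symbol. That gene table was used for names and for which genes neighbour each other. The array's own genome build was not given in the sources used here, so no coordinates are printed.

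Groups and replicate numbers came from the sample titles and the genotype label. The series' design counts mice, 8 and 7, so each array is taken as 1 animal. Sex, strain, litter and batch were not given in the sources used here. The genotype difference was fitted with limma 3.58.1 in R 4.3.3, as lmFit and eBayes without trend, on all 15 arrays and with no covariate. Tests were two-sided, and a probe set passed at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are knockout minus wild type, with the moderated standard error (SE) of the fit, and folds are 2 to the power of the log2 change. For named genes and lists, 1 probe set stood for a gene, the one with the highest mean over all arrays, and 1082 genes had more than 1. Single genes and list means were also tested by an exact permutation test over all 6435 splits of 15 samples into groups of 7 and 8. The smallest p this test can give is 0.000155.

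The tests, the alternatives unless said otherwise, the rule for the genes to be named and 35 gene lists were fixed before the data were examined. The lists covered nephron segments, cell junctions, injury, immune cells, metabolism, stress responses, the circadian clock, sex-biased genes, other tissues, the grainyhead family and named neighbours of Grhl1. Of their 562 genes, 501 were measured. The 33 lists with 3 or more measured genes were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. The list of red blood cell genes and the list that holds Xist alone fell below this size. Counts of list members are given over all probe sets tested and adjusted over the list alone. Another 7 lists, for liver, adrenal cortex and medulla, brown fat, general fat, heat shock chaperones and cold-induced RNA-binding proteins, were written after the first results had been seen. Genes within 20 Mb of Grhl1 on chromosome 12 were set against all other placed genes with Fisher's exact test.

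The text names Grhl1 and the rest of its family, up to 12 genes past the threshold in each direction and, since fewer than 10 passed, the 10 genes with the smallest unadjusted p. In each list it could take up to 4 members past the threshold or, where none passed, the 2 with the smallest unadjusted p. Genes named outside this rule were chosen after their values were seen. A sample was counted as holding liver or adrenal cortex transcripts where its list mean exceeded the median of all samples by more than 1 log2 unit, and as holding Y-linked transcripts where the mean of the Y-linked genes lay above the midpoint between its lowest and highest value.

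The fit was tested on simulated values for the 23521 probe sets at these group sizes, with 200 probe sets changed. It recovered 82.1% of 67 probe sets changed by 0.5 log2 units, 97.0% of 67 changed by 1 and 100% of 66 changed by 1.5, and 4.12% of its 194 calls were false. With 1 list lowered by 0.3, that list alone passed camera, and no list passed with nothing changed. The simulated values were drawn independently for each gene and without sex structure. Lists whose genes vary together, as in the real samples, were therefore not tested by it.

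The alternatives were a trended robust variance, a filter on dim probe sets, all probe sets of the table, 1 probe set per gene, the mean of a gene's probe sets, array weights, median centring, a second quantile normalization, a rank-sum test, a minimum fold of 1.5, covariates for Y-linked and circadian transcripts, windows of 5, 10 and 40 Mb around Grhl1, an unadjusted p under 0.001 as the call there, and leaving out each sample. Leaving out samples with liver or adrenal transcripts, taking only the samples with or without Y-linked transcripts, covariates for liver and adrenal transcripts, the Y-linked covariate for the genes around Grhl1 and the circadian covariate for the lists were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.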

Results

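Transcripts were measured in whole kidney RNA of 8 Grhl1 knockout mice, replicates 8 to 15, and 7 wild-type mice, replicates 1 to 7, all about 6 months old. The single comparison in this design asks which kidney transcripts differ when Grhl1 is lost. Values are log2 RMA summaries per probe set. Differences are knockout minus wild type, group values are means ± SD with n = 7 wild-type and n = 8 knockout mice, and all tests are two-sided.

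Grhl1 was lower in each of the 8 knockout kidneys than in every wild-type kidney. Its 1 probe set read 5.25, 5.09, 5.04, 4.96, 5.02, 5.20 and 5.05 in wild-type replicates 1 to 7, and 4.66, 4.60, 4.77, 4.80, 4.80, 4.92, 4.40 and 4.68 in knockout replicates 8 to 15. The means were 5.09 ± 0.10 and 4.70 ± 0.16, a difference of -0.38 (SE 0.07) or 1.3-fold lower, with an exact permutation p of 0.000311. In limma over all probe sets the adjusted p was 0.113, so the difference missed the threshold there. The probe set was dim, with 41.7% of all probe sets below its wild-type mean and 34.1% below its knockout mean. Which part of the gene was deleted was not given in the sources used here, and a probe set outside that part would check nothing about the labels. The other measured members of the family did not pass in limma. Grhl2 differed by 0.02 (adjusted p = 0.998), Grhl3 by 0.13 (adjusted p = 0.973, 0.06 without knockout replicate 8), Tfcp2 by 0.23 (adjusted p = 0.826), Tfcp2l1 by 0.02 (adjusted p = 0.998) and Ubp1 by -0.05 (adjusted p = 0.979), and the signs of Grhl2 and Tfcp2l1 turned with the Y-linked mean as a covariate (-0.011 and -0.0088), among other settings.

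Greb1, an oestrogen-responsive gene that lies on chromosome 12 as Grhl1 does, rose 3.08-fold in the knockout kidneys, from 5.18 ± 0.32 to 6.80 ± 0.28 (difference 1.62, SE 0.14, limma adjusted p = 5.30e-05). Rec8, a cohesin subunit best known from meiosis and encoded on chromosome 14, was 2.07-fold lower, at 5.02 ± 0.14 against 6.08 ± 0.19 (difference -1.05, SE 0.08, limma adjusted p = 2.23e-05). Cys1, which encodes the cilium-associated protein cystin and is disrupted in a mouse model of polycystic kidney disease, was 1.51-fold lower, at 6.80 ± 0.13 against 7.40 ± 0.22 (difference -0.60, SE 0.09, limma adjusted p = 0.0330). Greb1 and Rec8 separated the groups without overlap, and Cys1 did not. These were the 3 of 23521 probe sets past the threshold, 1 higher and 2 lower, while 1305 (5.55%) had an unadjusted p under 0.05. In 29 probe sets the groups did not overlap, where chance gives 7.31, a share of 0.0311%. The exact rank-sum test called 0 probe sets, with 1152 at an unadjusted p under 0.05 and a smallest adjusted p of 0.236. The call of Cys1 was lost in 13 of the 15 fits that left out 1 sample, with adjusted p from 0.00183 to 0.130 in limma.

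**Figure D1:**
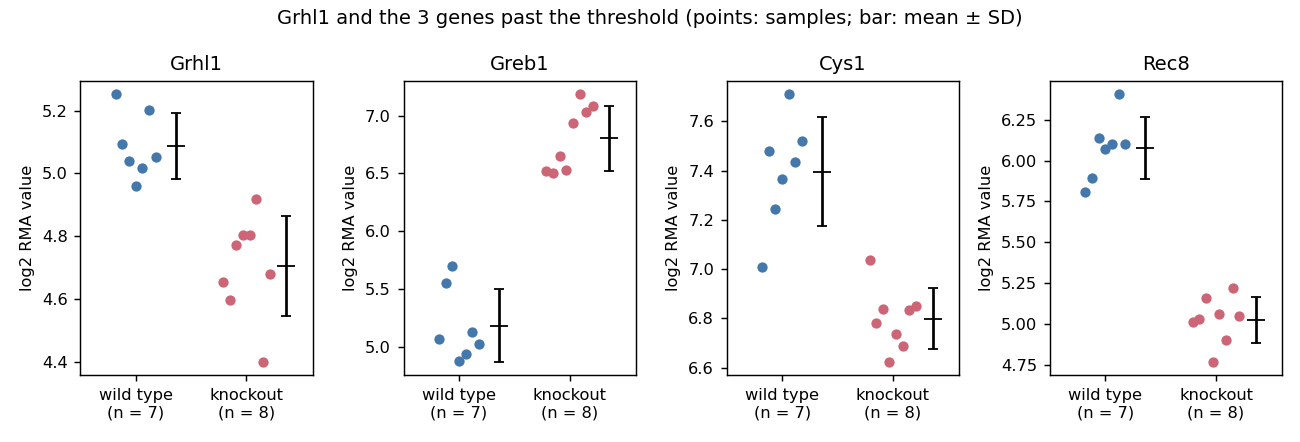
Log2 RMA values (vertical axes) of Grhl1, Greb1, Cys1 and Rec8 in 7 wild-type and 8 knockout kidneys, with a point per sample and bars for the mean ± SD. Greb1 averages 5.18 in wild-type and 6.80 in knockout kidneys, and Rec8 averages 6.08 and 5.02.

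Of the 10 genes with the smallest unadjusted p, the other 7 did not pass in limma. Apart from Grhl1 these were Srebf1, a regulator of lipid synthesis (-0.36, SE 0.06, adjusted p = 0.0968), Kidins220, a membrane scaffold of neurotrophin signalling (-0.40, SE 0.07, adjusted p = 0.0968), Cmpk2, a mitochondrial nucleotide kinase (-0.40, SE 0.07, adjusted p = 0.0983), the kinase gene Nim1k (0.30, SE 0.05, adjusted p = 0.113) and the predicted genes Gm3993 (0.89, SE 0.15, adjusted p = 0.0968) and Gm16685 (0.54, SE 0.10, adjusted p = 0.113).

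Genes with low p-values were concentrated on chromosome 12 around Grhl1. Within 20 Mb of it, 9 of 173 measured genes (5.20%) had an unadjusted p under 0.001 in limma, against 44 of 21821 genes elsewhere (0.202%), an odds ratio of 27.1 (95% interval 11.5 to 57.5, Fisher's exact p = 3.08e-10). Of these 9 genes, 3 were higher and 6 lower in knockout kidneys. They include Grhl1 itself, the targeted gene, and 8 others. Among these 8, Dnajb9 also belongs to the unfolded protein response list below and counts in both patterns. The higher genes were Greb1, 27 genes away from Grhl1, Gm4419 (0.57, 4 genes away) and Taf1b, a subunit of the RNA polymerase I initiation factor (0.38, 1 gene away). The lower genes were Grhl1, Cys1 (2 genes away), Kidins220 (5 genes away), Cmpk2 (12 genes away), 5730507C01Rik (-0.62, 14 genes away) and Dnajb9, a co-chaperone of the endoplasmic reticulum (-0.61, 87 genes away). Counting only genes past the adjusted threshold, 2 lay near Grhl1 and 1 elsewhere (Fisher's exact p = 0.000184). In the list of named neighbours of Grhl1, with 67 of 72 genes measured, 3 rose (Greb1, Taf1b and Adam17) and 5 fell (Cys1, Kidins220, Cmpk2, Rsad2 and Klf11) adjusted over the list alone, and 1 rose and 1 fell over all probe sets.

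**Figure D2:**
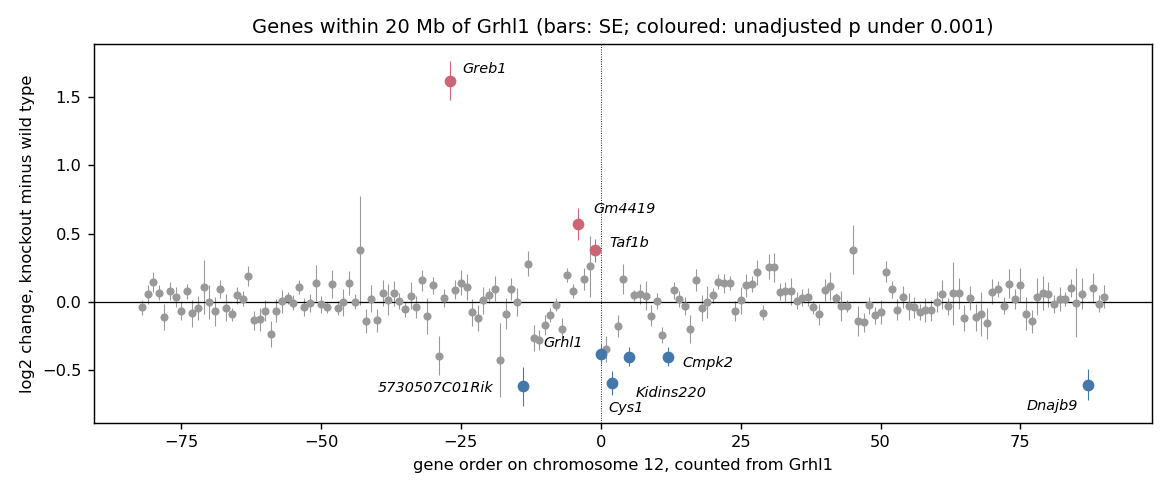
Log2 change with SE bars (vertical axis) of the 173 genes within 20 Mb of Grhl1 in their order on chromosome 12 (horizontal axis, counted from Grhl1), with the 9 genes at an unadjusted p under 0.001 in red where higher and in blue where lower. Greb1 stands at 1.62, 27 genes away from Grhl1, and Dnajb9 at -0.61, 87 genes away.

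Genes of the unfolded protein response, which raise folding capacity in the endoplasmic reticulum, were lower in knockout kidneys. The mean over 14 measured members was 9.37 ± 0.13 against 9.69 ± 0.21, a mean change of -0.32 (SE 0.06 over members), 1.25-fold lower, with 13 of 14 members lower. The list passed limma's camera at the preset correlation (adjusted p = 4.76e-15), and missed the threshold otherwise (adjusted p = 0.110 with an estimated correlation). Fry's test for change in 1 direction gave an adjusted p of 0.0522, and its test for change in either direction passed (adjusted p = 0.00590). The exact permutation p of its mean was 0.00357, and 0.122 after adjustment over the lists, here with the list that holds Xist alone included. Adjusted over the list alone, 8 members fell, and 0 did over all probe sets in limma. These were the chaperone Hspa5 (-0.50), its co-chaperones Dnajb9 (-0.61) and Sdf2l1 (-0.60), the degradation factor Herpud1 (-0.43), the secreted factor Manf (-0.40), Creld2 (-0.67), and the transcription factors Xbp1 (-0.31) and Atf4 (-0.14). Trib3 was the member that was not lower, at 0.07. The mean change was -0.35 within the 10 samples with Y-linked transcripts and -0.18 within the 5 without them.

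Of the 33 lists tested, 8 passed camera at the preset correlation, 2 higher and 6 lower. With an estimated correlation 0 passed, with 2 at an unadjusted p under 0.05, and fry called 0 in 1 direction, again with 2 at an unadjusted p under 0.05. Fry's test for change in either direction called 2, the named neighbours of Grhl1 (adjusted p = 1.64e-07) and the unfolded protein response (adjusted p = 0.00590). Other splits of the samples into groups of these sizes gave 8 lists at the median, and the 22 of them with the same makeup of Y-linked transcripts gave 3. With the Y-linked mean as a covariate, camera at the preset correlation called 10 lists, 6 of them among the 8. Cell cycle (adjusted p = 0.0510) and cholesterol synthesis (adjusted p = 0.0753) lost the call there. Male-biased genes (-0.14, adjusted p = 0.0162), NRF2 targets (-0.07, adjusted p = 0.0273), urothelium (-0.09, adjusted p = 0.0389) and intercalated cells (-0.06, adjusted p = 0.0389) gained it. These 4 missed the threshold with an estimated correlation (adjusted p = 0.381, 0.381, 0.653 and 0.653). The Bmal1-phase clock genes averaged -0.25, with 5 of 5 lower and Cry1 (-0.33) and Nfil3 (-0.44) fallen adjusted over the list alone (camera adjusted p = 0.00775; adjusted p = 0.559 with an estimated correlation). Immediate early genes averaged -0.07, with 14 of 17 lower and Dusp1 at -0.30 (adjusted p = 0.0170; adjusted p = 0.559 with an estimated correlation). Genes of the distal convoluted and connecting tubule averaged 0.08, with 14 of 16 higher, among them Pvalb at 0.23 and Trpm7 at 0.08 (adjusted p = 0.0170; adjusted p = 0.915 with an estimated correlation). Macrophage and myeloid genes averaged -0.07, with 16 of 18 lower and Fcgr3 at -0.19 and Tyrobp at -0.20 (adjusted p = 0.0196; adjusted p = 0.937 with an estimated correlation). Cell cycle genes averaged 0.08, with 17 of 19 higher and Mcm2 at 0.10 and Tyms at 0.17 (adjusted p = 0.0257; adjusted p = 0.915 with an estimated correlation). Cholesterol synthesis genes averaged -0.06, with 12 of 15 lower and Fdps at -0.13 and Lss at -0.14 (adjusted p = 0.0348; adjusted p = 0.937 with an estimated correlation). Lymphocyte genes averaged -0.20, with 12 of 16 lower and the immunoglobulin genes Jchain at -0.996 and Ighm at -1.19 (adjusted p = 0.0471; adjusted p = 0.937 with an estimated correlation). Apart from the clock genes, no member of these last 6 lists passed adjusted over the list alone. Their calls were also lost in some of the fits that left out 1 sample, while each mean kept its sign. The lymphocyte call ended in 10 of 15 fits that left out 1 sample, all but those without wild-type replicates 2, 5 and 7 and knockout replicates 13 and 15, with means from -0.31 without knockout replicate 15 to -0.15 without knockout replicate 9 and adjusted p up to 0.294. The cholesterol synthesis call ended in 7 of 15, without wild-type replicates 2, 4 and 5 or knockout replicates 8, 11, 13 and 15, with means from -0.10 without wild-type replicate 7 to -0.041 without wild-type replicate 4 and -0.023 without wild-type replicate 5, and adjusted p up to 0.455. The macrophage and myeloid call ended in 5 of 15, without wild-type replicates 6 and 7 or knockout replicates 9, 10 and 11, with means from -0.13 without knockout replicate 15 to -0.044 without knockout replicate 9 and -0.034 without wild-type replicate 6, and adjusted p up to 0.216. The distal tubule call ended in 5 of 15, without wild-type replicates 1 and 4 or knockout replicates 13, 14 and 15 (0.056 to 0.10, adjusted p up to 0.0928), and the cell cycle call in 4 of 15, without wild-type replicate 7 or knockout replicates 13, 14 and 15 (0.054 to 0.10, adjusted p up to 0.170). The immediate early call ended in 2 of 15, without wild-type replicates 6 and 7, with means from -0.11 without wild-type replicate 4 to -0.045 without wild-type replicate 6 and adjusted p up to 0.0911.

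**Figure D3:**
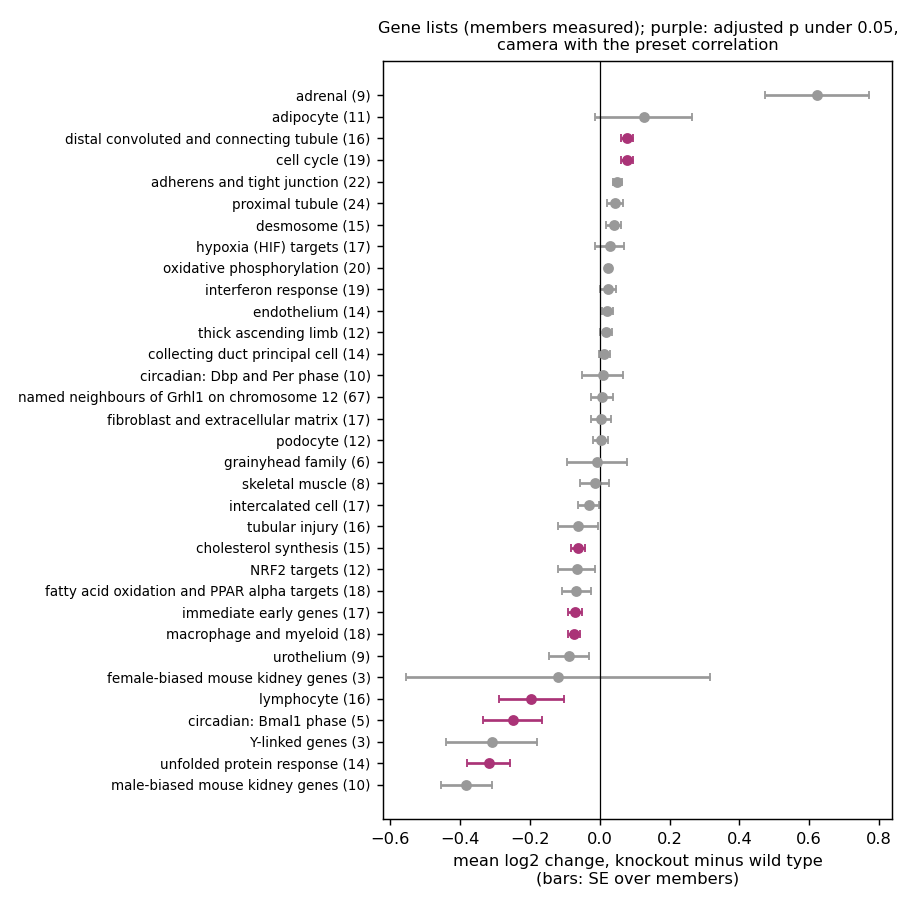
Mean log2 change with SE bars over members (horizontal axis) of 33 gene lists (vertical axis, measured members in brackets), with lists past camera's threshold at the preset correlation in purple. The unfolded protein response list stands at -0.32, and the adrenal list, which did not pass, at 0.62.

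The other 25 lists did not pass camera without a covariate, and among them were most nephron segments. Proximal tubule genes averaged 0.04, thick ascending limb 0.02, principal cells 0.01, intercalated cells -0.03, podocytes 0.0025 and urothelium -0.09. Junction genes averaged 0.04 for desmosomes and 0.05 for adherens and tight junctions. Tubular injury genes averaged -0.06 (0.02 without wild-type replicate 7), fibroblast and matrix genes 0.0044, endothelium 0.02 (0.0015 without wild-type replicate 1 to 0.06 without wild-type replicate 6), skeletal muscle -0.01 and interferon response genes 0.02. Among metabolic and stress lists, oxidative phosphorylation averaged 0.02 (0.01 without wild-type replicate 1), fatty acid oxidation -0.07 (0.03 without wild-type replicate 7, -0.11 without wild-type replicate 1), NRF2 targets -0.07, hypoxia targets 0.03 (0.01 without knockout replicate 12) and the Dbp and Per clock phase 0.0089. The grainyhead family averaged -0.01, with Grhl1 fallen adjusted over the list alone, and the named neighbours of Grhl1 averaged 0.0070 (0.0010 without wild-type replicate 7 to 0.01 without wild-type replicate 2). The mean and the median had opposite signs for intercalated cells, podocytes, the grainyhead family and the female-biased genes, and camera's direction was down for podocytes and for the neighbours of Grhl1 where the mean lay above 0. Leaving out 1 sample also turned the sign of several of these means. Principal cells ranged from -0.03 to 0.08 (8 of 15 fits turned, without wild-type replicates 1 to 5 or knockout replicates 13 to 15). Podocytes ranged from -0.04 to 0.05 (7 turned, without wild-type replicates 1 to 4 or knockout replicates 13 to 15). Fibroblast and matrix genes ranged from -0.04 to 0.04 (7 turned, without wild-type replicates 1, 2, 4 and 5 or knockout replicates 13 to 15). The Dbp and Per phase ranged from -0.04 to 0.07 (5 turned, without wild-type replicates 1, 3 and 7 or knockout replicates 11 and 12). Skeletal muscle ranged from -0.03 to 0.0066 (4 turned, without wild-type replicate 1 or knockout replicates 9, 10 and 12). The grainyhead family ranged from -0.02 to 0.02 (3 turned, without wild-type replicates 6 and 7 or knockout replicate 9). The thick ascending limb ranged from -0.02 to 0.07 (2 turned, without knockout replicates 14 and 15). Intercalated cells ranged from -0.07 to 0.02 (2 turned, without wild-type replicates 6 and 7). Interferon response genes ranged from -0.01 to 0.06 (2 turned, without wild-type replicate 4 or knockout replicate 15). Camera at the preset correlation called adherens and tight junctions in 5 of 15 such fits (without wild-type replicates 6 and 7 or knockout replicates 8, 9 and 12, 0.06 to 0.09, smallest adjusted p = 0.00403). It called urothelium in 4 (without wild-type replicates 3 and 5 or knockout replicates 8 and 9, -0.14 to -0.11, smallest adjusted p = 0.0231) and NRF2 targets in 3 (without wild-type replicate 6 or knockout replicates 9 and 12, -0.07 to -0.06, smallest adjusted p = 0.0373). The junction list was at 0.03 without knockout replicate 14, and urothelium at -0.04 without wild-type replicate 7. In the adipocyte list, which averaged 0.13 (0.06 without knockout replicate 13), Ucp1, the uncoupling protein of brown fat, rose by 1.28 and the hormone gene Lep fell by 0.68 on the log2 scale adjusted over the list alone, and neither passed over all probe sets.

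The samples also differed in ways that cross the genotypes. Y-linked transcripts were present in 10 samples, 5 of each genotype (means of 3 measured genes from 8.37 to 8.68), and low in wild-type replicates 6 and 7 and knockout replicates 13, 14 and 15 (3.96 to 4.26), where Xist read 11.4 to 11.6. The Y-linked list averaged -0.31, male-biased genes -0.38 and female-biased genes -0.12, with 2 of 7 wild-type and 3 of 8 knockout samples lacking Y-linked transcripts. Leaving out 1 sample, male-biased genes ranged from -0.80 to -0.06 and passed camera in 6 of 15 fits (without wild-type replicates 6 and 7 or knockout replicates 8, 9, 10 and 12, smallest adjusted p = 0.00772). The Y-linked list ranged from -0.84 to 0.11 (above 0 without knockout replicates 13, 14 and 15) and the female-biased genes from -0.50 to 0.35 (above 0 without wild-type replicates 6 and 7 or knockout replicates 8, 9, 10 and 12). Transcripts of liver were high in wild-type replicates 3 and 7 and knockout replicate 10, with means of 8.16, 10.8 and 8.04. Transcripts of adrenal cortex were high in wild-type replicates 2 and 3 and knockout replicates 10 to 13, with means from 7.36 to 9.61 against 4.70 to 5.06 elsewhere. The adrenal list fixed beforehand averaged 0.62, and 4 of the 6 samples with such transcripts were knockouts. It passed camera without wild-type replicate 2 (1.01, adjusted p = 0.0183) or 3 (1.04, adjusted p = 0.0140), and averaged 0.25 without knockout replicate 13. The Bmal1-phase list averaged -0.07 without these 6 samples (camera adjusted p = 0.444), the lymphocyte list -0.05 (adjusted p = 0.870) and the cholesterol synthesis list -0.04 (adjusted p = 0.297). Without the 3 samples with liver transcripts the immediate early genes averaged -0.04 (adjusted p = 0.132) and the macrophage and myeloid genes -0.04 (adjusted p = 0.196). Within the 10 samples with Y-linked transcripts the cell cycle list averaged -0.02 (adjusted p = 0.671) and the distal convoluted and connecting tubule list 0.04 (adjusted p = 0.0954).

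**Figure D4:**
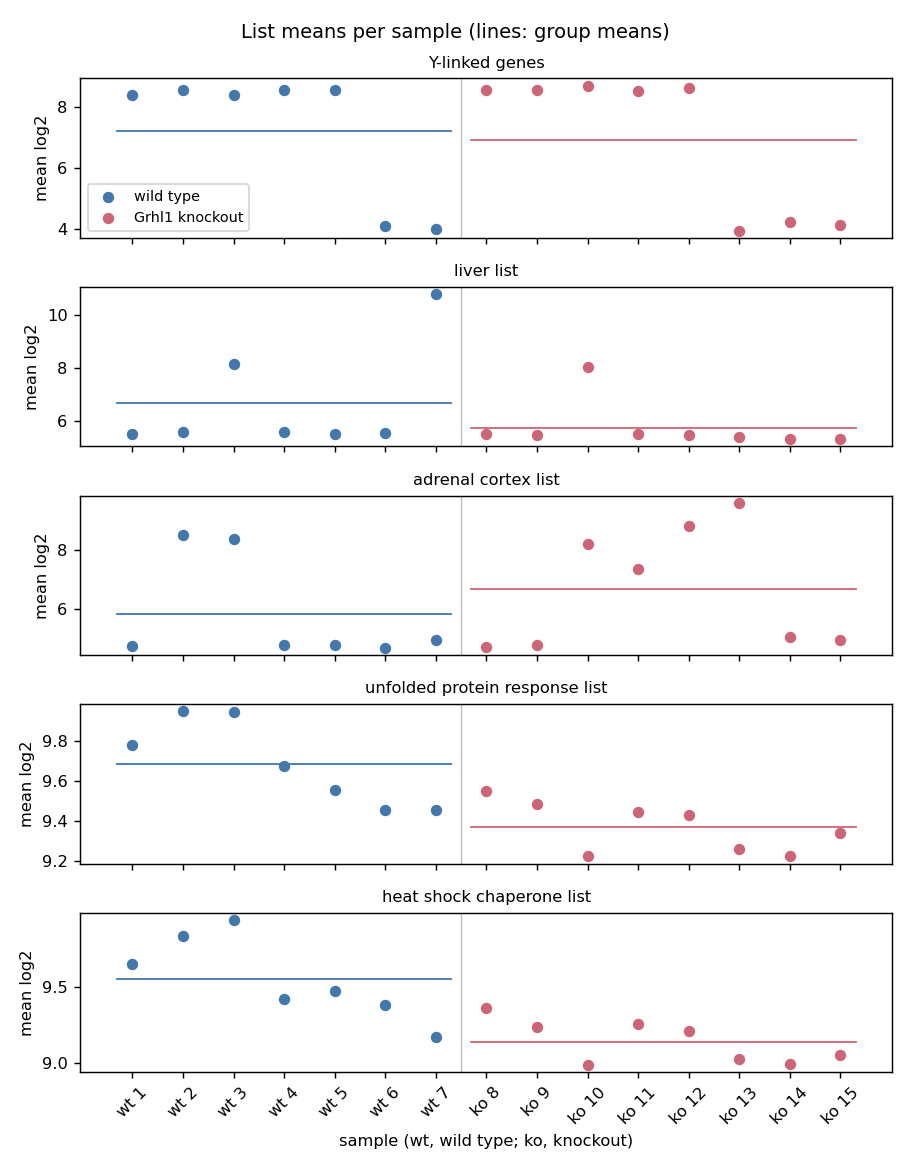
Mean log2 value (vertical axes) of 5 gene lists in each of the 15 samples (horizontal axis), with wild type in blue, knockout in red and lines at the group means. The liver list reads 10.8 in wild-type replicate 7, and the unfolded protein response list averages 9.69 in wild-type and 9.37 in knockout samples.

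Greb1 kept its difference across these subsets. It was 1.40 within the 10 samples with Y-linked transcripts (limma adjusted p = 0.0342), 2.02 within the 5 without them (adjusted p = 0.0161) and 1.78 without the 7 samples with liver or adrenal transcripts (adjusted p = 0.0173). Rec8 differed by -0.9999 (adjusted p = 0.00346), -1.20 (adjusted p = 0.621) and -1.02 (adjusted p = 0.161) in the same 3 subsets, and Cys1 by -0.56 (adjusted p = 0.240), -0.69 (adjusted p = 0.621) and -0.50 (adjusted p = 0.991). With the Y-linked mean as a covariate in limma, 14 probe sets of 12 genes passed, 5 genes higher and 7 lower, and all 3 calls above were among them. Besides Kidins220, Gm3993 and Srebf1, the added genes were Gm4419 (adjusted p = 0.00293), Taf1b (adjusted p = 0.0474), the phosphatase gene Dusp9 (adjusted p = 0.0349), Txndc11 of the endoplasmic reticulum (adjusted p = 0.0415), and the chaperone genes Hspa8, by 3 probe sets (smallest adjusted p = 0.00453), and Chordc1 (adjusted p = 0.0102). Hspa8 and Chordc1 were lower in knockout kidneys, with changes of -0.47 at the Hspa8 probe set with the smallest p and -0.50. The Hspa8 probe set with the highest mean, which stands for the gene here, changed by -0.22 and missed the threshold (limma adjusted p = 0.0536). Gm4419, Taf1b, Dusp9, Txndc11, Hspa8 and Chordc1 were named after their values had been seen, as were 5730507C01Rik, Adam17, Rsad2 and Klf11 and the unfolded protein response genes other than Dnajb9 and Manf.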

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

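The tests of flanking chromosome, of sex makeup and of liver or adrenal tissue in this part were chosen after the results had been seen, as was the reading of the unnamed probe sets.

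The largest differences lay in probe sets outside the comparison because they had no gene name here. Over all 41345 probe sets, 4 unnamed ones passed limma. Probe set 17280184 differed by -3.63 (SE 0.19, adjusted p = 1.33e-07), from 7.27 ± 0.25 to 3.64 ± 0.49, and its ID lies between those of 1700030C10Rik and Itgb1bp1. Probe set 17274308 differed by -3.13 (SE 0.26, adjusted p = 4.90e-05), from 9.52 ± 0.79 to 6.39 ± 0.20, between Odc1 and Hpcal1. Probe set 17274401 differed by -0.71 (SE 0.10, adjusted p = 0.0236), between Gm6943 and Asap2, and probe set 17502858 by -0.61 (SE 0.09, adjusted p = 0.0236), between Inpp4b and Rnf150. In 3 of the 4 the neighbours by ID are genes within 20 Mb of Grhl1 on chromosome 12. Of placed probe sets with consecutive IDs, 98.4% share a chromosome, but the positions of these 4 were not given in the sources used here. Gm3993 was not placed on a chromosome here either. Its probe set ID, 17274385, lies between those of 5730507C01Rik and Gm4419, which are within 20 Mb of Grhl1. This reading of Gm3993 was made after its value had been seen.

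The first pattern weighed is the cluster of low p-values around Grhl1. Sex makeup as the cause is argued against by the Y-linked covariate, with which 12 genes near Grhl1 had an unadjusted p under 0.001 in place of 9, although genes elsewhere went from 44 to 90 and the odds ratio from 27.1 to 18.0 (95% interval 8.78 to 33.8). Without the 7 samples with liver or adrenal transcripts, the mean size of change of these 9 genes was 0.647 (SE 0.148 over genes), against 0.620 with them. The 9 were picked for a low p in data that include the remaining samples, which favours a large value. Liver or adrenal tissue as the whole cause therefore stays open. In the 8 remaining samples 2 of the 173 genes, Grhl1 and Greb1, and 12 of 21821 elsewhere reached that p (odds ratio 21.2, 95% interval 2.29 to 96.6, Fisher's exact p = 0.00526). Grhl1 is the targeted gene, so Greb1 was the only neighbour among them. This p therefore does not show that a cluster of neighbours held in these samples. No draw of 100 splits of the samples other than the real one reached 9 such genes (1 of 100, highest other 7). Among the 22 other splits with the same makeup of Y-linked transcripts the highest was 3. This argues against chance but does not exclude it, as the draws were few and the targeted gene is among the 9. Flanking chromosome of another strain carried with the targeted allele stays open, as does an effect of the allele itself on nearby genes, and strain was not given in the sources used here. That 0 of 18338 windows of 173 neighbouring genes elsewhere held as many as these 9 (highest elsewhere 2, on chromosome 8) restates the cluster and does not tell the 2 apart.

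The genotype difference of Inmt, a methyltransferase gene on chromosome 6, varied with the Y-linked mean by 0.15 per log2 unit (SE 0.02, limma adjusted p = 0.0412), the 1 probe set past the threshold of 1661 at an unadjusted p under 0.05. With Y-linked transcripts coded as present or absent, limma called 0 probe sets (1655 at an unadjusted p under 0.05), and Inmt had an interaction of 0.68 (SE 0.10, adjusted p = 0.263). The present-or-absent coding was run first for this part and gave no call, and the continuous mean, already used as the covariate, was taken after that, so the call rests on the coding. Inmt differed by 0.04 with Y-linked transcripts and by -0.65 without them, where there were 2 wild-type and 3 knockout samples.

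A single sample lay far from the rest of its group in 14 of 220 groups tested, where chance gives about 1 in 20, or 11. For genes it was 11 of 154 groups and for lists 3 of 66. In wild-type samples these were Nim1k in replicate 4 (6.10, others 5.89 to 5.98), Grhl3 in replicate 4 (5.52, others 5.71 to 5.80), Dsg1b in replicate 5 (3.86, others 3.33 to 3.54), Cdh16 in replicate 6 (12.004, others 11.78 to 11.85) and Ndufa5 in replicate 1 (7.73, others 7.87 to 7.97). In knockout samples they were Ighm in replicate 15 (13.13, others 9.57 to 10.69), Trpm7 in replicate 10 (10.20, others 10.02 to 10.09), Srxn1 in replicate 10 (8.99, others 9.15 to 9.28), Ndufa5 in replicate 11 (8.23, others 7.93 to 8.04), and Grhl3 (6.34, others 5.63 to 5.85) and Ubp1 (9.09, others 8.80 to 8.92) in replicate 8. Among the lists, tubular injury (7.91, others 7.22 to 7.51) and fatty acid oxidation (10.74, others 9.89 to 10.25) were highest in wild-type replicate 7, the sample with the highest liver list, and macrophage and myeloid genes (7.97, others 7.36 to 7.64) in knockout replicate 15.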

How the results depend on the processing

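Settings that used subsets by liver, adrenal or Y-linked transcripts or covariates for liver and adrenal transcripts were chosen after the results had been seen. No paired analysis was possible because the groups share no replicate numbers. The count of probe sets past limma's threshold stayed within 1.5 times of 3 in 24 of 33 settings. It was 0 without the dimmer probe sets (771 at an unadjusted p under 0.05), which by construction removes Greb1 and Rec8, and 0 by the exact rank-sum test (1152 at an unadjusted p under 0.05). It was 7 over all probe sets, 14 with the Y-linked covariate, 8 with Y-linked, liver and adrenal covariates, 1 without the genes near Grhl1, 1 without the 7 samples with liver or adrenal transcripts and 1 in the 5 samples without Y-linked transcripts. Leaving out 1 sample gave 2 to 6, with 6 without knockout replicate 8. Subtracting each array's median left 2 calls, 1 higher and 1 lower. The largest shift of the median change over settings was 0.018. Over its settings Greb1 ranged from 1.40 to 2.02 (past in 30 of 31), Rec8 from -1.20 to -0.997 (29 of 32) and Cys1 from -0.69 to -0.50 (9 of 32). Grhl1 was lower in 31 of 31 settings (-0.52 to -0.34), with adjusted p from 0.0691 to 0.991. Fisher's exact p for the genes near Grhl1 stayed under 0.05 in 27 of 27 settings, from 3.08e-10 to 0.0234. The smallest came from the call at an unadjusted p under 0.001. The other settings used the adjusted threshold, where leaving out 1 sample left 1 to 4 genes called near Grhl1, Greb1 in each fit. They thus rest on few genes. The filter on dim probe sets and the rank-sum test, with 0 calls, were not among them. The count of lists stayed within 1.5 times of 8 in 20 of 27 settings. It was 0 with the estimated correlation and 3 without the 6 samples with adrenal transcripts, and leaving out 1 sample gave 5 to 10, with 5 without wild-type replicate 4 or knockout replicates 11, 13, 14 or 15. The unfolded protein response list kept its call in 26 of 27 settings (-0.36 to -0.18) and lost it with the estimated correlation (-0.32, adjusted p = 0.110). All 26 used camera's preset correlation, so they do not test the assumption on which the call rests. With an estimated correlation and the Y-linked covariate together, the list also missed the threshold (camera adjusted p = 0.143). Of 2487 values of 76 named genes over the settings, 2403 kept direction and side of the threshold, 27 lost the call, 10 gained it and 47, in 18 genes, changed sign. In the 5 samples without Y-linked transcripts these were Jchain 0.38, Egln3 -0.10, Egfl7 -0.074, Tyms -0.032, Lss 0.054, Dsg1c -0.079, Acta1 0.22, Cox5a -0.067, Aqp3 -0.071, Xist -0.017, Abcc3 -0.16 and Grhl2 -0.070, and the lymphocyte (0.16) and cholesterol synthesis (0.072) lists. In the 10 samples with them they were Cyp2e1 0.056, Eif2s3y 0.045, Uty 0.090, Xist -0.017, Abcc3 -0.00052 and Tfcp2l1 -0.042, and the cell cycle list (-0.019). Without the 6 samples with adrenal transcripts they were Lss 0.012, Aqp3 -0.037 and Grhl2 -0.0039, and without the 7 with liver or adrenal transcripts Aqp3 -0.056 and Tcf21 0.032. With the Y-linked covariate they were Grhl2 -0.011 and Tfcp2l1 -0.0088, and with all 3 covariates Tfcp2l1 -0.0064. Leaving out 1 sample, Aqp4 ranged from -0.25 to 0.00091, Eif2s3y from -0.98 to 0.016, Uty from -1.03 to 0.050, Xist from -0.030 to 1.55, Abcc3 from -0.052 to 0.85, Grhl2 from -0.026 to 0.080 and Tfcp2l1 from -0.024 to 0.066. Apart from the removal of Greb1 and Rec8, the cause was not tested. No signal over background was given, so what is absent and what is dim cannot be separated here.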

Other observations

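The tests of sex makeup, of the 7 samples, of liver, of adrenal gland, of loss of Grhl1 and of more brown fat in this part were chosen after the results had been seen, as were the lists of heat shock chaperones, brown fat, general fat, liver, adrenal cortex and adrenal medulla.

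Heat shock chaperones were lower in knockout kidneys in 16 of 16 measured genes, with a mean of 9.14 ± 0.14 against 9.55 ± 0.27 and a mean change of -0.41 (SE 0.10 over members, exact permutation p = 0.00218, n = 7 and 8). Hspa1b differed by -1.47, Hspa1a by -1.15, Hsph1 by -0.69, Chordc1 by -0.53, Hspb1 by -0.48 and Dnajb1 by -0.36, and none of these passed limma over all probe sets. Brown fat genes were higher in 9 of 11, with a mean change of 0.36 (exact permutation p = 0.00482), led by the lipid elongase Elovl3 at 1.32 and Ucp1 at 1.28, with Otop1 at 0.40, Cidea at 0.28 and Dio2 at 0.23. Both lists were written after some of their genes had been seen to differ, Ucp1 among them, so neither p is independent evidence. General fat genes averaged -0.03 (exact permutation p = 0.877), with 6 of 8 higher, a median of 0.06, Adipoq at 0.03 and Lep at -0.68. The liver list averaged -0.91 (exact permutation p = 0.201), the adrenal cortex list 0.85 (p = 0.401) and the adrenal medulla list 0.23 (p = 0.741).

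One hypothesis for higher Ucp1 and Elovl3 beside lower chaperone transcripts is a lower tissue temperature in knockout mice. The cold-induced transcript Cirbp differed by 0.22 with an exact permutation p of 0.0556, Rbm3 was not measured, and this cannot be told apart from no effect on so few genes. More brown fat attached to the knockout kidneys may be another source. The other 9 brown fat genes had a median change of 0.195 (SE 0.0516), with 7 higher and 2 lower. That lies under the bound of 0.5 written for this test, but the 9 include genes with high wild-type levels, such as Ppargc1a (10.8), and dim ones, such as Lhx8 (3.90), that would not show a small share of fat. That reason does not cover Cidea, Cox8b and Otop1, with wild-type levels of 8.04, 8.62 and 6.53 against 8.61 for Ucp1. Their smaller differences (0.28, 0.22 and 0.40) go against more fat. These 3 genes varied with Ucp1 over the 15 samples once each genotype's mean was removed (correlations 0.65, 0.66 and 0.91), as a varying share of brown fat would give, and what they read in kidney free of fat is not known. General fat genes as a list did not rise (mean -0.03, median 0.06, 6 of 8 higher), which also goes against more fat. Some of them read high in wild-type kidneys, such as Car3 (12.2). The condition that most of the 9 brown fat genes be at informative levels was set after the value had been seen. Without it the bound would count against more brown fat. More brown fat stays open as an explanation.

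The second pattern weighed is the lower unfolded protein response list. For this list taken alone, 1 of 100 splits reached the real size of 0.318 (highest other 0.261), but it had the smallest p of 33 lists. Its exact permutation p was 0.122 after adjustment over these and the list that holds Xist alone, so chance stays open. Sex makeup as the whole cause is argued against by a mean change of -0.354 (SE 0.0698) within the 10 samples with Y-linked transcripts, no smaller than over all samples. Without the 7 samples with liver or adrenal transcripts the mean change was -0.216 (SE 0.0426), with 13 of 14 members lower. SEs here are over members, which vary together (estimated correlation 0.386), and do not measure the spread between mice. With 4 mice left per genotype, liver or adrenal tissue as the whole cause stays open. With the Dbp and Per mean as a covariate the change was -0.320 (SE 0.0622), but that mean differed by 0.0089 between genotypes and could not have moved it. The condition that it differ, without which this value would count against time of day, was set after the value had been seen. Time of day stays open, with lower Bmal1-phase genes, as do handling and dissection, which were not tested. That loss of Grhl1 lowers these genes is therefore a hypothesis.

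The third pattern weighed is the presence of liver transcripts in 3 samples and adrenal transcripts in 6. Pieces of liver may explain the first. At least 93.75% of liver genes lay over 1 log2 unit above the other samples (15 of 16 in wild-type replicate 3 and knockout replicate 10, all but Apoh), with Alb at 12.2, 13.4 and 12.2. The 3 samples were picked by the mean of this same list, so that share largely restates the choice and is no separate test. Pieces of adrenal gland may explain the second. Cortex rises were 2.77 to 5.34, but the 6 samples were picked by the cortex list itself. The medulla list was not used to pick them, and its rises were 0.752 to 3.52. The lowest medulla rise, in knockout replicate 11 (SE 0.223 over 5 genes), lay under the bound of 1 written for this test, by more than 1 SE and less than 2. As first written that bound counted against adrenal tissue in that sample. The margin of 2 SE, which leaves the question open, was set after the value had been seen. Loss of Grhl1 as the whole cause is argued against by the 3 wild-type samples that held such transcripts, while an effect on their frequency cannot be told apart from none, at 4 of 8 knockout and 3 of 7 wild-type samples (Fisher's exact p = 1).

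In the 100 splits of the samples, the real one included, 3 reached its 3 probe sets, a share under 0.05 but from few draws. The other splits among these called 1106 and 2328 probe sets. Both put all 5 samples without Y-linked transcripts in the group of 7, so their calls are confounded with sex makeup. Among the 23 splits with the same makeup of Y-linked transcripts the highest other called 1, which argues against chance. With the Y-linked covariate 1 of 100 reached 14 (highest other 3), which argues against chance, again from few draws. For the lists passing camera at the preset correlation chance cannot be excluded, since 54 of 100 splits reached 8 (highest other 21). Among the 23 splits with the same makeup of Y-linked transcripts 3 reached 8, the real one included (highest other 10, median of the others 3), a share that is smaller but does not exclude chance either.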
